A study of Mus musculus with 2 samples.

How the data were processed

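RNA was sequenced from mouse breast tumour cells, given in the labels as the line AS0574 in 2 forms. One form lacked Rnf8 and Trp53, the other lacked both with Rnf8 put back, and each had 1 library. Per the labels' protocols, total RNA was taken from the cell lines with a column kit, its quality was assessed on a Bioanalyzer, and libraries were made by standard Illumina TruSeq methods. The submitters' processing notes name STAR 2.4.0f1, SAMtools 0.1.18, bedtools, DESeq2 and the mouse build mm10 (GRCm38), with no role or order. The counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Without strand, reads of a gene and of an antisense or overlapping gene cannot be told apart, and near-identical genes can share reads.

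The authors deposited raw read counts per gene, which are whole numbers and not normalized. The authors also deposited RPKM values (reads per kilobase of gene, scaled to the library's total of counted reads) for the same 23562 gene symbols and libraries. The 2 sets were compared. Dividing each count by its RPKM and its library's total gave 1 whole-number length for each of the 20176 genes with a read, to within 1.35e-08 bases, so each RPKM was the count scaled by the column total and a gene length. Columns were matched to samples by the sample titles, and 0 columns of other samples were left out. The library totals were 57263401 and 48607808 counted reads, on 18390 genes with a read in the Rnf8-null and 18769 in the Rnf8-complemented library. The 10 genes with most reads took 4.25% and 6.44% of the counts. A scaling to the library total passes on any shift in a few abundant genes to all others, which the scaling alternatives address.

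From these values the difference log2(RPKM + 1), Rnf8-null minus Rnf8-complemented, was computed per gene. A fold on that scale understates the difference of low genes, so folds of single genes are given as ratios of RPKM. Genes with a mean RPKM of at least 1 over the 2 libraries entered counts and lists, and a gene was called higher or lower at a log2 difference of at least 1 or at most -1, a 2-fold rule. With 1 library per group there is no spread between replicates, so no test between conditions was run and no gene is said to have changed. Exact Poisson 95% intervals on the counts were scaled to RPKM, and exact conditional binomial (Clopper-Pearson) 95% intervals were used for ratios of reads per library total. Both cover counting error only and no spread between cultures. They can be too narrow even for counting error, because reads without molecular identifiers are not independent molecules. No fold is given against a library with 0 reads.

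The design, the 2-fold rule, 33 gene lists and 10 alternatives were fixed before the data were examined. For each list the median log2 difference of its measured members was set against 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list with at least 5 measured members and a percentile under 2.5 or over 97.5 was said to stand apart, which describes these 2 libraries and is no test. Of the 33 lists 28 could be judged, 4 had too few members and 1, the mitochondrially encoded genes, had no member in the data analysed here. Several lists share genes. Members at 0 reads in a library were set to 3 reads as a check, which moved no list median by more than 0.0108. Only 7 list members were at 0 and 3 reads are small beside the added 1 RPKM, so little movement was possible. The pseudocount alternatives bear on low values instead. The files held counts beside RPKM. RPKM was kept as the main unit, as the design stated, and the counts served for intervals and for TMM scaling (edgeR 4.0.16 in R 4.3.3).

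The genes named in the text follow a rule also fixed before the data were examined. It takes Rnf8 and Trp53, the 15 highest and the 15 lowest genes by log2 difference among genes with an RPKM of at least 5 in the higher library, and up to 4 members of each list with the largest absolute difference. Genes outside that rule are members of the lists given to complete a count, or were chosen after their values were seen. The latter are Cdh1, Trp63, Acta2, Esr1, Vim, Fn1, Notch2, Jag1, Adam17, Rbpj, Hey1, Hey2, Heyl, Hes5, Cdkn1a, Mdm2, Ptprc, Gata3, Tjp1, Lig4, Ifitm3 and Dsp in the comparison, and Dsp, Ifnb1 and all genes of the families among the closing observations. Some genes that the rule takes are not reported here. Positions come from GENCODE vM21 on GRCm38, the build named in the submitters' notes, and 22218 symbols matched RefSeq genes of that build.

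Of gene models shorter than 200 bases, 651 had a mean RPKM of at least 1, 646 of these had a position and 565 lay inside another gene. Such models took 1.60% of the counts in the Rnf8-null and 1.38% in the Rnf8-complemented library. Among models with at least 50 reads in both libraries, 41 shared their pair of counts with another model. The alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a mean RPKM of at least 5, a median difference set to 0, equal RPKM sums, equal upper quartiles, random lists matched in 5 bins or not matched, and a 4-fold rule. After seeing the data, TMM scaling, leaving out models under 200 bases, and leaving Rnf8 out of the DNA double-strand break list and Trp53 out of the p53 target list were added.

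The computation was tested on simulated data for this comparison. Poisson counts were drawn for both libraries from 1 rate per gene, the mean of the rates in the 2 real libraries, at the real library totals. In the simulated data 12593 genes passed the filter on mean RPKM. The 2-fold rule recovered 61 of 65 genes planted at 3-fold and 70 of 70 at 6-fold, called 0 of 64 planted at 1.5-fold, and called 8 of 12394 unchanged genes. Of 200 lists drawn at random from all these genes, the planted ones included, 9 (4.5%) were said to stand apart, about the rate that the percentile limits set. A list of unchanged genes shifted by 2-fold reached percentile 100. These draws hold counting error only, with no spread between cultures. Few genes in them were changed, unlike in the real libraries, so the list results do not show how the list rule behaves there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.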

Results

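The data were gene-level RNA sequencing values from 2 forms of what the labels give as 1 mouse mammary tumour cell line, AS0574. By the labels the first form carried deletions of Rnf8 and Trp53, and the second was the same line with Rnf8 put back. Rnf8 encodes a ubiquitin ligase that acts at DNA double-strand breaks, and Trp53 encodes the tumour suppressor p53. Each form was represented by 1 library, so there were no replicates, no difference below has a replicate check, and no p-value was computed. The Rnf8-null library held 57263401 counted reads and the Rnf8-complemented library 48607808. At these depths 3 reads on a gene of 2000 bases corresponded to 0.0262 RPKM (reads per kilobase of gene, scaled to the library total) in the Rnf8-null library and 0.0309 in the Rnf8-complemented library. Intervals are exact 95% limits on the read counts and cover counting error only.

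The comparison asked how the transcriptome of tumour cells lacking Rnf8 differed from that of the cells with Rnf8 put back. Rnf8 itself was reported first, because its level checks which library had Rnf8 put back. Rnf8, a protein-coding gene on chromosome 17 from 29614790 to 29644991 of GRCm38, stood at 10.5 RPKM (9.94 to 11.1, 1224 reads) in the Rnf8-null library and at 596 RPKM (591 to 601, 58868 reads) in the Rnf8-complemented library. That was 56.7-fold higher with Rnf8 put back (interval 53.5 to 60.0) and a log2 difference, null minus complemented, of -5.70. Trp53, on chromosome 11 from 69580359 to 69591873, was read at 6.15 RPKM in the Rnf8-null and 4.69 RPKM in the Rnf8-complemented library, a ratio of 1.31 (interval 1.19 to 1.44). The counts are per gene, so they do not show which part of either gene was read. Rnf8 in the Rnf8-null library stood close to the median of the genes counted as expressed there (9.78 RPKM), so its reads do not check its deletion, and those of Trp53 do not check that of Trp53. In the Rnf8-complemented library Rnf8 stood far above the median of those genes (10.47 RPKM). Neither library came from cells with Rnf8 intact, so no difference below is set against an unaltered level of Rnf8. Which exons were deleted and from which species Rnf8 was put back are not given in the sources used here.

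Genes of epithelial cells separated the libraries. The keratin genes Krt7 (chromosome 15, 101411043 to 101430313), Krt18 (chromosome 15, 102028180 to 102032027) and Krt8 (chromosome 15, 101996698 to 102004482) encode intermediate filaments of simple epithelia. They stood at 1649, 1762 and 1126 RPKM in the Rnf8-null library and at 0.182, 0.294 and 0.296 RPKM in the Rnf8-complemented library. Epcam, an epithelial adhesion molecule, had 27083 reads against 1, and Cdh1, which encodes E-cadherin and was chosen after its values were seen, had 41879 against 7. The fold differences were 9079 for Krt7 (interval 5411 to 16607), 5996 for Krt18 (3882 to 9817) and 22989 for Epcam (4126 to 908062), the last with 1 read in the lower library. Of 29 measured epithelial junction and keratin genes, 28 were at least 2-fold higher in the Rnf8-null library, 0 were lower and 1, Tjp1, lay within 2-fold. Their median log2 difference was 5.45, above all 10000 random lists matched on mean expression. Over all 31 listed genes, without the filter on low values, the median was 4.79 (percentile 100). Among the listed genes below the filter, Dsp, chosen after its values were seen, had fewer reads in the Rnf8-null library.

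Most measured markers of both mammary epithelial layers were higher in the Rnf8-null library. Of 19 luminal markers, 17 were at least 2-fold higher, and the list median of 5.003 lay above all 10000 random lists. Examples were Ltf, which encodes the milk protein lactoferrin, at 635 against 0.143 RPKM, and Krt19 at 417 against 0.0449 RPKM. The luminal list shares 8 genes with the epithelial list, and its 1 lower member was Gata3, a luminal transcription factor, at 0.191 against 7.99 RPKM. Of 14 basal and myoepithelial markers, 12 were higher and 0 lower, with a median of 3.32, again above all 10000 random lists. Over all 24 listed basal genes, without the filter on low values, the median was 1.08 (percentile 100), and over the 7 with a mean RPKM of at least 5 it was 5.08. The basal regulator Trp63 (3 against 48 reads), the myoepithelial actin gene Acta2 (5 against 18) and the luminal receptor gene Esr1 (20 against 106), chosen after their values were seen, lay below the filter with fewer reads in the Rnf8-null library. Krt17 had 22162 reads against 1, Krt14 stood at 229 against 0.335 RPKM, and Lamb3, a laminin chain of the epithelial basement membrane, at 75.6 against 0.337 RPKM. Mammary progenitor and tumour stem cell genes were also higher on balance (8 higher and 2 lower of 15, median 1.03, percentile 99.93), among them Sox10 with 9049 reads against 1, Aldh1a3 at 32.3 against 0.259 RPKM and Ly6a at 56.9 against 1.77 RPKM. That median was 0.12 over 22 genes without the filter (percentile 99.65) and 2.41 with a mean RPKM of at least 5.

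The other highest-ranked genes included Wfdc2 (923 against 0.465 RPKM), the tight junction claudins Cldn4 (402 against 0.0454) and Cldn3 (381 against 0.0977), and Gabrp, a GABA receptor subunit (373 against 0.0753). They also held S100a14 (344 against 0.456 RPKM) and Lad1 (46214 reads against 2). Klk6, a kallikrein protease, had 27587 reads in the Rnf8-null library and 0 in the other. Plet1os had 13733 reads against 0, but it is annotated as an antisense transcript and cannot be told from its partner without strand.

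**Figure D1:**
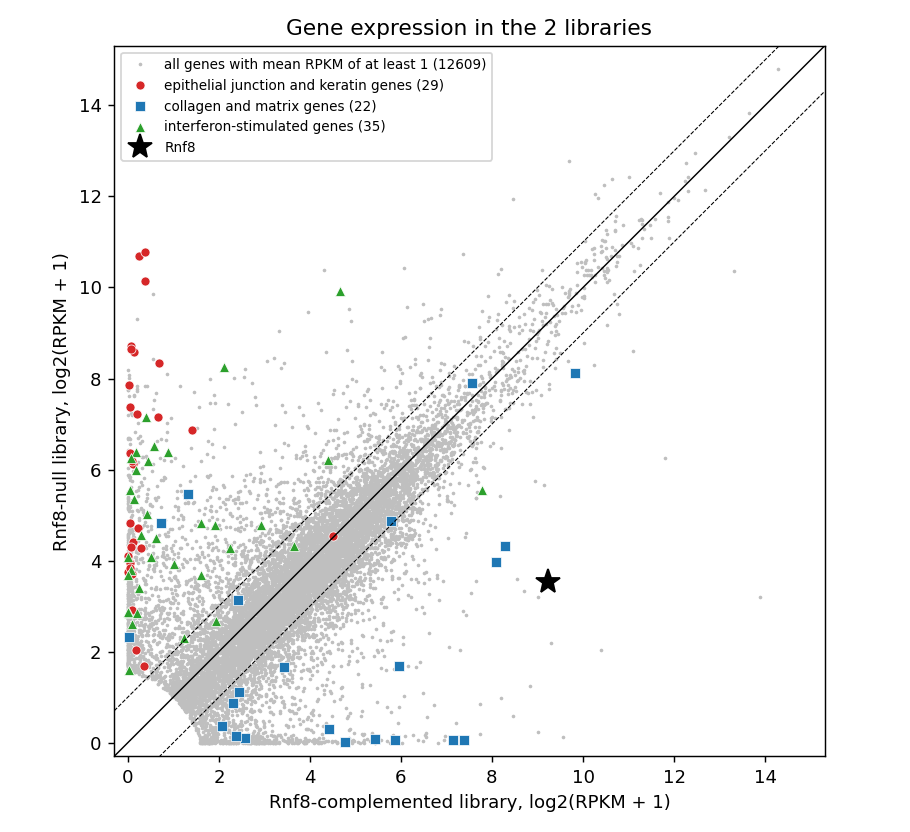
Expression of each gene with a mean RPKM of at least 1 in the Rnf8-complemented library (horizontal) and the Rnf8-null library (vertical), as log2(RPKM + 1), with the line of equality solid and the 2-fold lines dashed. Of the epithelial junction and keratin genes 28 of 29 lie above the upper dashed line, of the collagen and matrix genes 16 of 22 lie below the lower one, and Rnf8 lies far below it.

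Genes of mesenchymal cells and of the extracellular matrix went largely the other way. Col3a1 (chromosome 1, 45311538 to 45349706), a fibrillar collagen of connective tissue, stood at 0.0342 RPKM in the Rnf8-null library and 139.7 in the Rnf8-complemented library, 4089-fold lower in the null (interval 2518 to 7155). Col5a2 stood at 0.0435 against 165 RPKM, and Sparc, a secreted matrix glycoprotein, at 3.56 against 632. Of 22 collagen and matrix genes, 16 were at least 2-fold lower in the Rnf8-null library and 3 higher, namely Lama5, Col7a1 and Lama4, and the list median was -2.02, below all 10000 random lists (-4.04 with a mean RPKM of at least 5). Of 19 mesenchymal and EMT genes (EMT, epithelial-mesenchymal transition), 12 were lower and 4 higher, with a median of -1.76, also below all 10000. Without the filter, over 30 genes, that median was -0.31, at percentile 0.4. Pdgfrb, a receptor of mesenchymal cells, stood at 0.0389 against 46.6 RPKM, and the transcription factor gene Twist1 had 2 reads against 1548.

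The mesenchymal list held members that went both ways. Its 4 higher members were Tnc (124 against 8.41 RPKM), Fn1 (126 against 38.2), S100a4 and Postn. Vim, which encodes the mesenchymal filament vimentin and was chosen after its values were seen, was abundant in both libraries at 376 against 725 RPKM. Of 6 fibroblast markers, 4 were lower and 1 was higher (median -1.51, percentile 0.210, and -0.45 over 16 genes without the filter), and of that list 5 genes are shared with the matrix list and 5 others with the mesenchymal list. Further genes among the 15 lowest in the Rnf8-null library were Htra1 (0.505 against 349.6 RPKM), Igfbp7 (1.38 against 456), Fscn1, an actin-bundling protein (0.969 against 291), Prss23 (0.805 against 214) and Ckap4 (0.0479 against 123). Serpinb9g (15 against 19755 reads) and Serpinb9e (11 against 11657) have closely related neighbours that can share reads, so their separate values are uncertain. The same holds for Mir669e and Snord118, small RNA genes that ranked among the 15 lowest, because reads of an overlapping transcript can be counted to them.

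Notch signalling, which sets cell fate in the mammary gland, was represented by a list of components and a list of targets. Among the components, the receptors Notch3 (16.7 against 2.08 RPKM, 8.03-fold, interval 7.46 to 8.64), Notch4 (8.77 against 0.970, 9.04-fold, 8.11 to 10.1) and Notch1 (3.91 against 0.0613, 63.7-fold, 44.8 to 94.0) were higher in the Rnf8-null library. The fourth receptor gene, Notch2, chosen after its values were seen, was read at 4.24 against 8.77 RPKM, 2.07-fold less in the Rnf8-null library (interval 1.97 to 2.17), which is within 2-fold on the log2(RPKM + 1) scale (-0.90). The ligand gene Jag1 (12.2 against 5.27 RPKM) and the protease gene Adam17 (36.5 against 16.9) were also higher, and Numbl (5.67 against 26.7) was lower. With 22 of 28 components within 2-fold, among them the nuclear effector Rbpj at 29.8 against 30.7 RPKM, the component list did not stand apart (median -0.04, percentile 80.1).

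Notch target genes were higher in the Rnf8-null library on balance. Of 14 measured targets, 6 were at least 2-fold higher and 2 lower, with a median of 0.86 at percentile 99.91 of random lists (1.38 with a mean RPKM of at least 5). The target list shares Notch3 and Dtx1 with the component list and Ccnd1 and Myc with the Wnt list. Notch3, given above as a receptor, is among the 6 higher targets. Nrarp (chromosome 2, 25180758 to 25183339), a feedback regulator of the pathway, stood at 41.7 against 0.1598 RPKM (261-fold, interval 169 to 428), the repressor gene Hes1 at 33.4 against 2.47 (13.6-fold, 11.6 to 15.9) and Ccnd1, which encodes cyclin D1, at 145 against 13.4 (10.8-fold, 10.5 to 11.3). Snai2, which is also in the mesenchymal list, was lower at 0.0347 against 9.58 RPKM, and so was Gata3. The targets Hey1, Hey2, Heyl and Hes5, chosen after their values were seen, had at most 32 reads in the Rnf8-null and 56 in the Rnf8-complemented library. The epithelial and mesenchymal lists, with medians of 5.45 and -1.76, differed between the same 2 libraries.

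**Figure D2:**
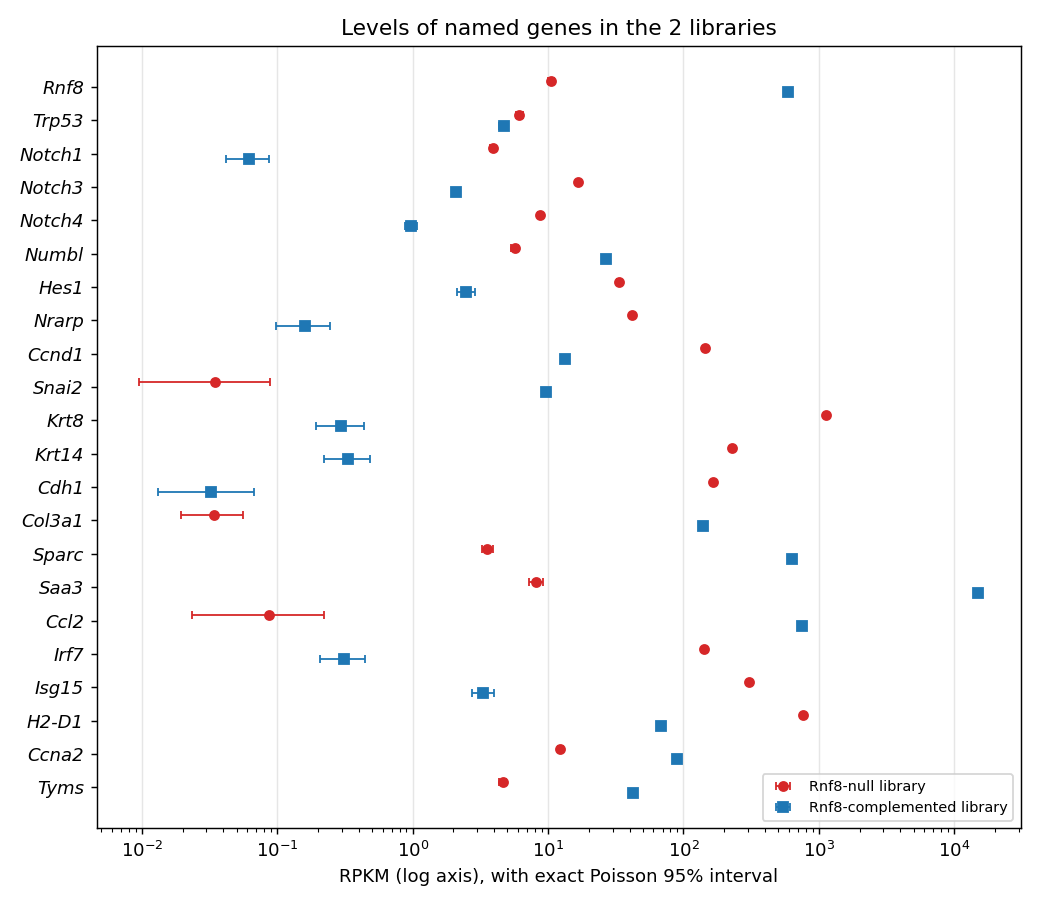
RPKM of 22 genes in the Rnf8-null library (circles) and the Rnf8-complemented library (squares) on a log axis, with exact Poisson 95% intervals that cover counting error only. Notch1, Hes1 and Nrarp lie to the right in the Rnf8-null library, and Rnf8, Col3a1 and Saa3 lie to the right in the Rnf8-complemented library.

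Genes of the dividing cell were lower in the Rnf8-null library. Of 31 G2 and M phase genes 24 were at least 2-fold lower and 0 higher (median -1.51), and of 31 S phase genes 19 were lower and 0 higher (median -1.21). Both medians lay below all 10000 random lists. Ccna2 (chromosome 3, 36564865 to 36572150), which encodes cyclin A2, stood at 12.3 against 89.3 RPKM (7.24-fold, interval 6.90 to 7.59), the kinetochore gene Nuf2 at 3.05 against 29.4 (9.64-fold, 8.79 to 10.6), and Tyms, thymidylate synthase, at 4.63 against 42.7 (9.22-fold, 8.65 to 9.84). Rrm2, a subunit of ribonucleotide reductase, stood at 11.01 against 79.0 RPKM. Replication-dependent histone genes were lower as well (9 of 11, 0 higher, median -1.61, below all 10000 random lists, and -0.75 over 21 genes without the filter), for example Hist1h2bk at 2.66 against 35.0 RPKM. The cell cycle and epithelial lists differed between the same 2 libraries, as did the mesenchymal list.

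The DNA double-strand break response list, in which Rnf8 belongs, was lower in the Rnf8-null library. Of 41 members 11 were at least 2-fold lower, including Rnf8 itself, and 1 was higher, namely Lig4. The median was -0.58 at percentile 0.470, and without Rnf8 it was -0.55 at percentile 1.07. Rad54l, a gene of homologous recombination, stood at 1.07 against 7.22 RPKM, the exonuclease gene Exo1 at 1.68 against 7.47, and H2afx, which encodes the histone marked at breaks, at 24.8 against 74.1. With only genes of a mean RPKM of at least 5 the list no longer stood apart (median -0.43, percentile 8.12). With TMM scaling its median was -0.37 and it still stood apart (percentile 0.71). In the same libraries the S phase and the G2 and M phase lists had lower medians (-1.21 and -1.51), and the epithelial and mesenchymal lists differed (5.45 and -1.76).

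Of 23 members of the p53 target list 5 were at least 2-fold higher in the Rnf8-null library, 4 were lower and 14 lay within 2-fold, and the list median stood apart as higher (median 0.33, percentile 99.15). By the labels both libraries lack Trp53, so this call is not read as a difference in p53 activity. The list holds Trp53 itself, which was the median member, and without it the median of the other 22 was 0.27, at percentile 98.55. The median of the whole list was 0.21 without the filter (percentile 99.03) and 0.52 with TMM scaling. Its higher members included Plk2 (66.9 against 6.77 RPKM), Gadd45a (54.9 against 5.80) and Perp, a desmosome-associated gene (78.4 against 12.0), while Fas was lower (0.213 against 6.41). Among targets close to the p53 circuit, chosen after their values were seen, Cdkn1a stood at 10.8 against 5.92 RPKM and Mdm2 at 22.4 against 19.2, both within 2-fold. Immediate early genes were higher on balance (10 higher and 3 lower of 23, median 0.73, percentile 99.98), led by Dusp6, a phosphatase of the ERK kinases (76.9 against 2.64 RPKM), and Ier3 (1386 against 66.4).

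Interferon-stimulated genes were higher in the Rnf8-null library. Of 35 members 32 were at least 2-fold higher and 1, Ifitm3, was lower, with a median of 3.56 above all 10000 random lists. Irf7 (chromosome 7, 141262706 to 141266481), a transcription factor of the interferon response, stood at 141 against 0.310 RPKM (454-fold, interval 316 to 678), Ifi44 at 82.7 against 0.127 (649-fold, 411 to 1096) and the ubiquitin-like modifier gene Isg15 at 302 against 3.32 (91.1-fold, 76.2 to 109.8). Oas1a had 8133 reads against 4, but Oas genes resemble one another and can share reads. MHC class I and antigen processing genes were higher too (11 higher and 1 lower of 17, median 1.21, percentile 99.97), such as H2-D1 (758 against 68.7 RPKM) and the proteasome activator gene Psme1 (227 against 27.0). H2 genes resemble one another closely, so their separate values are uncertain. The interferon and epithelial lists were higher in the same library, in which 3 leukocyte markers were also higher.

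Inflammatory genes went in both directions. The acute-phase gene Saa3 (chromosome 7, 46711998 to 46715700) stood at 8.14 RPKM in the Rnf8-null library and 15053 in the Rnf8-complemented library (1850.2-fold lower in the null, interval 1646 to 2088), and the monocyte-attracting chemokines Ccl2 and Ccl7 at 0.0867 against 749 and 0.175 against 516 RPKM. In contrast Csf3, which encodes the growth factor of granulocytes, stood at 183 against 0.483 RPKM. Of 29 NF-kB and inflammatory cytokine genes 12 were higher and 7 lower, and the list did not stand apart (median -0.10, percentile 48.7).

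TGF-beta targets were also divided, with 7 higher and 4 lower of 23 (median 0.27, percentile 96.6). Ctgf was higher in the Rnf8-null library (334 against 7.30 RPKM) and Tgfb2 lower (0.566 against 11.9). Among 9 Wnt targets 3 were higher and 3 lower (percentile 20.1), with Sox9 at 18.9 against 0.293 RPKM and Notum at 2.23 against 70.0. Filtered to a mean RPKM of at least 5, the 5 Wnt targets left had a median of 2.29 and stood apart. Hypoxia and glycolysis genes did not stand apart (percentile 18.9, 3 higher and 6 lower of 27), although the lactate transporter gene Slc16a3 was lower (0.779 against 105 RPKM) and the carbonic anhydrase gene Car9 higher (35.1 against 0.662).

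Nuclear-encoded oxidative phosphorylation genes stood apart as lower by a small amount. Their median was -0.33, against -0.17 over all genes, at percentile 0.830, with 1 of 38 members, Ndufa1 at 41.5 against 128 RPKM, past 2-fold. The median was -0.15 with the median of all genes set to 0 (percentile 0.83) and -0.10 with TMM scaling (percentile 0.38), and the list still stood apart in both. Matched in 5 bins of expression in place of 20, the list no longer stood apart (percentile 2.74), nor did it without matching (percentile 15.97). As deposited, all 41 ribosomal protein genes lay within 2-fold, the nearest to it being Rpl32 at a log2 difference of 0.98, which goes past 2-fold once the median of all genes is set to 0 (list median 0.25, percentile 89.1), and they stood apart as higher in 5 bins (percentile 98.12). Cholesterol synthesis (1 higher and 3 lower of 23, percentile 51.5), the unfolded protein response (3 and 4 of 23, 12.8) and apoptosis regulators (6 and 3 of 22, 94.4) did not stand apart. Trib3, of the unfolded protein response list, stood at 42.1 against 3.75 RPKM. Of 16 housekeeping genes 1, B2m, was higher and 4 were lower (percentile 12.5), for example Pgk1 at 581 against 1469 RPKM. Pgk1 and Ndufa1 lie on chromosome X, whose genes with a mean RPKM of at least 5 had a median of -0.72.

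**Figure D3:**
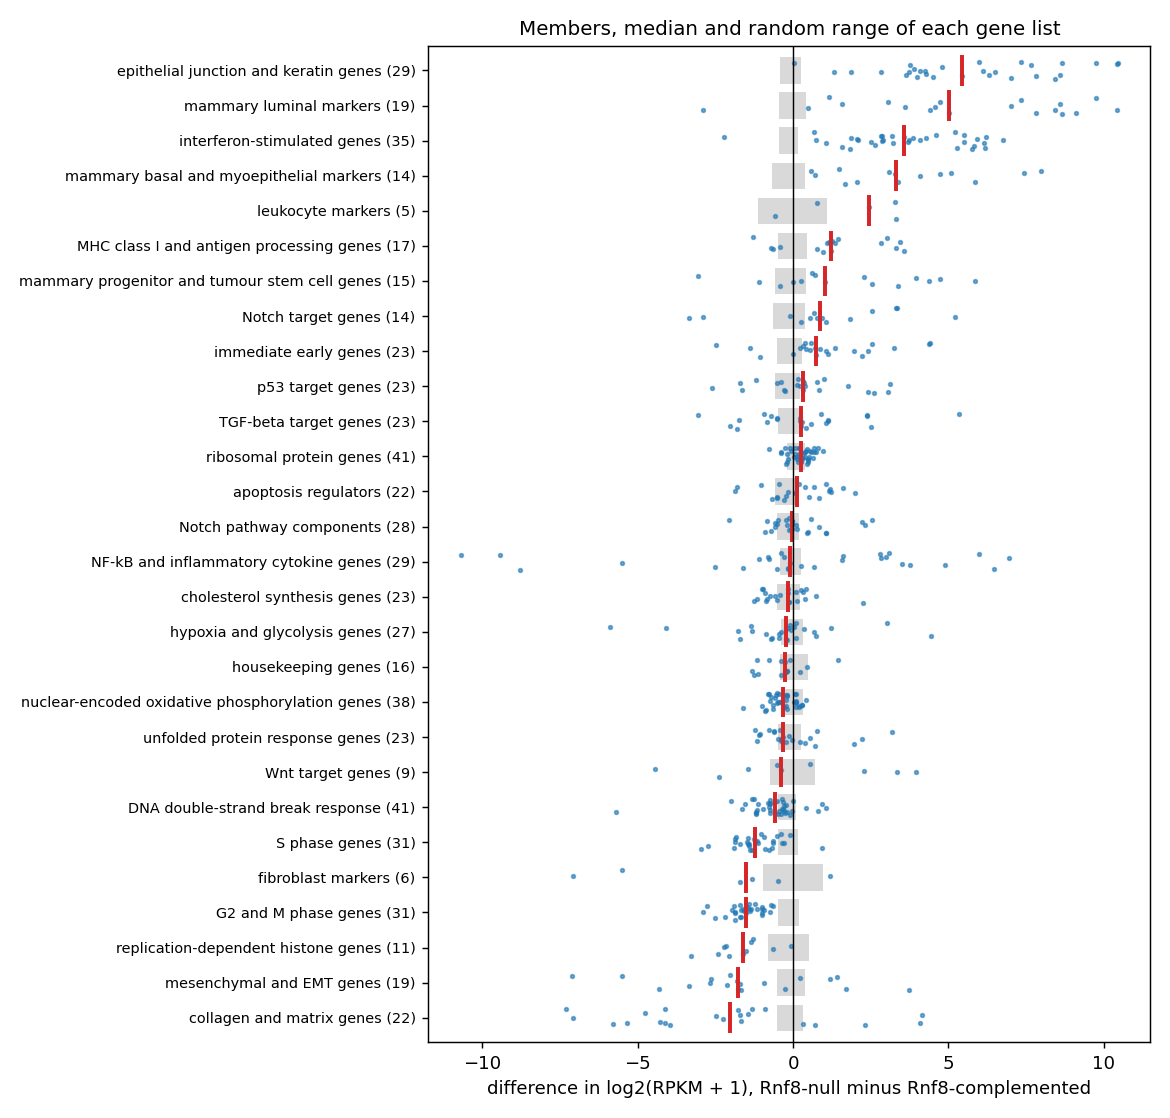
Difference in log2(RPKM + 1), Rnf8-null minus Rnf8-complemented, for the measured members (points) of the 28 gene lists with at least 5 of them, with the number of members in brackets, the list median (red line) and the range that holds 95% of the medians of matched random lists (grey bar). Medians run from -2.02 for collagen and matrix genes to 5.45 for epithelial junction and keratin genes.

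Markers of other cell types were examined because a tumour-derived line can hold other cells. Leukocyte markers had 5 measured members, of which S100a8 (175 against 17.1 RPKM), S100a9 (9.57 against 0.0600) and Cd74 (5.25 against 0.145) were higher in the Rnf8-null library (median 2.45, percentile 99.78). Without the filter on low values, over 21 members, the list did not stand apart (percentile 86.4), and Ptprc, the pan-leukocyte gene, chosen after its values were seen, had 0 reads against 1. Too few members for a percentile were measured of the endothelial (1), adipocyte (4), muscle and nerve (4) and sex-linked (2) lists. The adipocyte genes Fabp4 (0.163 against 92.4 RPKM), Plin4 (0.120 against 35.0) and Pparg (0.306 against 10.1) were lower in the Rnf8-null library and Lpl was higher. Of the muscle and nerve genes Tnni2 (6.48 against 0.124 RPKM), S100b and Mbp were higher, and the endothelial gene Flt1 stood at 13.0 against 6.49 RPKM. Xist (chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome, had 10 reads in the Rnf8-null and 17021 in the Rnf8-complemented library, and its antisense gene Tsix was given identical counts, so the pair cannot be told apart. No gene of the mitochondrially encoded list was listed in the data analysed here.

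Over all genes, 12609 had a mean RPKM of at least 1. Of these, 1866 (14.8%) were at least 2-fold higher in the Rnf8-null library, 2010 (15.9%) were lower and 8733 lay within 2-fold, and past 4-fold 980 were higher and 637 lower. Pearson's r of log2(RPKM + 1) across these genes was 0.708, and genes are not independent replicates. The median log2 difference was -0.17, and higher genes made up 48.1% of those past the rule. With that median set to 0 the share was 57.0%, and with TMM scaling of the counts, an alternative chosen after seeing the data, it was 58.4% with a median of 0.03. With equal RPKM sums it was 42.8%, so which direction held more genes depended on the scaling. Of the 28 lists judged 10 stood apart as higher and 8 as lower. Lists share genes and hold genes that vary together, unlike random lists, and all such statements describe these 2 libraries and not the conditions.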

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

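TMM scaling, leaving out gene models under 200 bases, and the 2 lists without Rnf8 or Trp53 were chosen after the data were seen, and the other alternatives before. Over 306 list checks in 11 alternatives run on the lists as fixed, the call was kept in 298, and 21 of 28 lists kept it in all 11. Not all of these checks could change a call. Setting the median to 0 shifts a list and its random lists by the same amount, so every percentile stayed the same. Equal sums, equal upper quartiles and TMM shift both nearly alike. Leaving out models under 200 bases changed no list median, so only the random lists could move. Fibroblast and leukocyte markers had too few members with a mean RPKM of at least 5, so 10 alternatives were run for each, and the fibroblast list kept its call in those 10. The DNA double-strand break list without Rnf8 and the p53 target list without Trp53 kept theirs. No called direction was turned by any alternative run. The log2 difference of Rnf8, -5.70 as reported, was -5.81 with a pseudocount of 0.1 RPKM, -5.28 with 5, -5.52 with the median set to 0, -5.83 with equal sums and -5.48 with TMM. Trp53, at 0.33, was 0.50 with the median set to 0 and 0.52 with TMM. These moves follow from the pseudocount or factor itself. A pseudocount of 5 RPKM left 1218 genes higher and 1015 lower, against 1866 and 2010, and the 4-fold rule 980 and 637, since both ask for a larger difference. With a mean RPKM of at least 5, 1273 of the 8997 genes left were lower. The same filter ended the call of the DNA double-strand break list (median -0.43, 24 members) and gave Wnt targets one (2.29, 5 members). Without a filter leukocyte markers lost theirs (0.00694). Matching in 5 bins and no matching ended the call of the oxidative phosphorylation list (-0.33) and gave ribosomal proteins one (0.25), and no matching gave TGF-beta targets one (0.27). A pseudocount of 5 RPKM shrank medians by more than 1.5 times in several called lists, such as luminal markers (3.27), basal markers (1.53), mesenchymal genes (-0.94), matrix genes (-1.01), interferon genes (1.94) and S phase genes (-0.81), and 0.1 RPKM enlarged others, such as basal markers (6.01) and matrix genes (-3.56), with the call kept. In the 5-bin and unmatched checks the medians are those reported, so the random lists moved, and for the other list calls the cause was not tested. Equal sums left 1924 higher and 2569 lower, and TMM 2181 and 1551. Lists that did not stand apart and had medians near 0 (Notch components, NF-kB, hypoxia and cholesterol genes) changed sign with scaling. No leave-one-out or replicate block could be run. No paired analysis was possible because each group has 1 library. Depth limits genes with few reads, where 3 reads on 2000 bases are 0.0262 and 0.0309 RPKM.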

Other observations

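The families and tests in this part were all chosen after the results were seen. Gene families were grouped by symbol, overlap the fixed lists in part, and were not tested for enrichment. Of 15 keratin genes 14 were at least 2-fold higher in the Rnf8-null library, including Krt23 with 1134 reads against 1, and Krt10 was lower, with 2 reads against 370. All 5 kallikrein genes measured were higher, with Klk10 at 3182 reads against 0 and Klk8 at 4060 against 2. Wfdc18, a secreted protein of the whey acidic protein family, had 6624 reads against 0, and all 3 Wfdc genes were higher. Of 9 claudins 6 were higher and 1, Cldn12, was lower. Dsp, which encodes the desmosome protein desmoplakin and had a mean RPKM below 1, also had fewer reads in the Rnf8-null library, 2 against 176. All 6 Serpinb9 genes were lower, but reads shared between them leave the separate values uncertain.

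Of 23 homeobox and patterning genes, put together after their values were seen, 14 were at least 2-fold lower in the Rnf8-null library and 4, Dlx4, Irx1, Irx2 and Irx3, were higher. Nr2f2 had 0 reads in the Rnf8-null and 3291 in the Rnf8-complemented library, Dlx1 0 against 1031, Hoxa3 0 against 827 and Shox2 2 against 3518. In contrast Irx1 stood at 95.6 against 26.0 RPKM.

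Most epithelial genes were near 0 in the Rnf8-complemented library, while the 41 measured mesenchymal and matrix genes stood in the Rnf8-null library at a median of 14.9% of their level in the other (quartiles 1.16% and 83.3%). A minority of other cells mixed into the Rnf8-complemented library is argued against by the 29 measured epithelial genes, whose level there was a median of 0.120% of that in the Rnf8-null library (quartiles 0.0257% and 0.532%), and a swap of the labels by Rnf8, 56.7-fold higher where it was put back. A separate cell population under one of the labels and a change of cell state after Rnf8 was put back may both account for it, and they cannot be told apart with 1 library per group. Either could leave genes on one side, as with 96 genes that had at most 2 reads in the Rnf8-null library and at least 5 RPKM in the other, and 128 genes the other way.

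X-linked genes were lower in the Rnf8-null library, where 10 reads were counted to Xist. Less silencing by Xist alone would make them higher there, not lower. Over genes with a mean RPKM of at least 5, the median log2 difference was -0.72 for 230 X-linked genes, and it ran over the 19 autosomes from -0.55 on chromosome 3 to 0.33 on chromosome 6. Chromosome-to-chromosome differences of any cause stay open, as X lay 2.499 SD below the mean of the autosome medians and chromosome 3 came close. A different X chromosome state could also account for it, but the 17021 reads counted to Xist in the Rnf8-complemented library were counted in equal number to its antisense gene Tsix and cannot be assigned to either, and 1 library per group cannot decide.

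Interferon-stimulated genes were high in the Rnf8-null library, with a median log2 difference of 3.56. Leukocytes in that library are argued against by the leukocyte markers fixed beforehand. The list holds 23 symbols, of which Adgre1 and Emr1 name the same gene, and 22 genes were in the data. The median of these 22 in the Rnf8-null library was 0.0299 RPKM, with 17 below 1 RPKM and Ptprc at 0 reads. However, S100a8 (175 against 17.1 RPKM), S100a9 (9.57 against 0.0600) and Cd74 (5.25 against 0.145) went with the interferon genes. A difference between the epithelial and mesenchymal states or a separate cell population under one of the labels may account for the pattern. So may the difference in Rnf8, which was not tested. These cannot be told apart here because they come in the same 2 libraries. Ifnb1, which encodes an interferon, had 6 reads against 2.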
